A study of Mus musculus with 21 samples.

How the data were processed

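Whole uteri of wild type C57BL/6J mice, an inbred laboratory strain, were profiled by RNA sequencing at 5 weeks of age, at 8 weeks of age and in old animals. Per the labels, every mouse was primed with pregnant mare serum gonadotropin, a placental hormone with follicle-stimulating activity, at a dose of 5 or 7.5 units, and the uterus was taken 48 hours later. Which animal received which dose is not given in the sources used here. Per the labels' protocols, the library kit was NEBNext Ultra, which does not keep the strand of a transcript, and sequencing used either single reads of 60 bp or paired reads of 150 bp on 2 Illumina instruments, without saying which library went to which instrument. RNA was purified with either of 2 kits, also without an assignment.

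The replicate numbers, the sample names and the ages of the old mice part each age group into the same 2 sets. The earlier set holds replicates 1 and 2 of each age, with aged mice of 60 to 75 weeks, and the later set holds the replicates from 3 to 7, with aged mice of 79 weeks. Any differences between the sets in instrument, kit and, for the aged group, age cannot be told apart.

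The authors deposited 1 table per sample in CPM, that is, counts scaled to a sum of 1e+06 over the listed genes in each column. The submitters' processing notes name fastp, STAR, featureCounts, edgeR and the mouse genome build GRCm38, with no versions and no roles, and whether counting used strand is not given in the sources used here. All 12791 genes listed had at least 10 reads in every library, so a gene silent in any library is not among them. For that reason Cdkn2a, a cell cycle inhibitor named in advance, was not analysed here.

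Of 21 files, 20 held values, and 1 held gene symbols in place of numbers. The column header of 15 of those 20 files names another sample of the series than the sample the file was attached to, in 2 cases of another age group and in 2 of the other set. The header of the other 5 names their own sample. In the order of the sample names, each of the 15 files holds the column named next, from aged through 5-week to 8-week samples. The first sample in that order, aged replicate 3, has no column. The last file, attached to 8w replicate 7, is the file without numbers. Headers and values would move together in such a shift, though its origin was not tested. The cases of another age group are 5w replicate 3, whose column lies in the file attached to aged replicate 7, and 8w replicate 3, whose column lies in the file attached to 5w replicate 7. In the cases of the other set the column correlated more with the set its header names: aged replicate 2 had a mean r of 0.885 with the earlier and 0.774 with the later set, and aged replicate 5 of 0.741 and 0.925. In 5w replicate 3 the mean log2(CPM + 1) of the cell cycle list was 5.40, against 4.92 to 6.38 in the other 5-week and 2.54 to 3.96 in the aged libraries of the later set. Its cholesterol list (4.17, against 4.95 to 5.73 and 4.16 to 4.71) and Wnt list (5.27, against 3.54 to 4.44 and 4.04 to 5.36) lay with the aged libraries, and its plasma cell list (5.00, against 3.70 to 4.29 and 5.36 to 7.13) lay between. Each library of the later set was then left out of the fit, and its distances to the mean of its younger group and to the aged mean of that set were compared. Of 3081 genes called between aged and 5-week uteri without 5w replicate 3, 48.1% lay nearer the aged mean in it, against 3.91% to 48.2% in the other 5-week and 47.6% to 90.4% in the aged libraries. Of 16 lists 9 did, against 0 to 3 in the other 5-week libraries. The measure did not set 5w replicate 3 apart from every other younger library. In 8w replicate 6, 47.5% of 2397 genes and 15 of 18 lists lay nearer the aged mean. In 8w replicate 4 these were 47.3% of 2356 genes and 2 of 14 lists, and in aged replicate 5, 47.6% of 3248 genes and 9 of 14 lists. The values thus do not settle the age of 5w replicate 3. In 8w replicate 3, 1.50% of 1463 genes lay nearer the aged mean, but no gene was called between 5 and 8 weeks, so which of these ages it has was not checked. Each column was taken as the sample its header names, and attaching columns by file was run as an alternative. Aged replicate 3 has no column under this mapping and was not analysed here, which left 7 libraries at 5 weeks, 7 at 8 weeks and 6 aged.

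Every CPM value was a whole multiple of the worth of 1 read, within a tolerance of 1e-06 of a read, for 100% of values in each library, so total reads could be recomputed. They ran from 12204573 to 14448283 in the 6 libraries of the earlier set and from 19100690 to 30689439 in the 14 libraries of the later set. The 10 most abundant genes took 3.59% to 7.17% of the reads in the earlier set and 5.59% to 9.37% in the later set. Of the gene identifiers, 12767 were found in GENCODE release 21 for mouse on GRCm38 and 24 were not, and coordinates are from that annotation. No libraries of the same group and set were near-copies: the lowest chi-square per degree of freedom over 29 pairs was 30.9.

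Testing used R 4.3.3 and limma 3.58.1 with statmod 1.5.0. CPM values were transformed to log2(CPM + 1), and genes with a CPM of at least 1 in at least 7 libraries were kept, which kept all 12791. A linear model with a term for each age group and a term for the set was fitted to all 20 libraries, and the contrasts were tested with limma's moderated test with a mean-dependent prior and robust estimation, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 fold changes are on the log2(CPM + 1) scale, which understates the change of low genes, and are given with standard errors. The 3 contrasts were aged against 8 weeks, aged against 5 weeks and 8 weeks against 5 weeks. An age by set interaction, with the difference of aged from the mean of both younger groups, was tested in the same way. On simulated data with 200 of 12791 genes changed, the test of aged against 8 weeks recovered 9%, 53% and 97% of changes of 1.5-fold, 2-fold and 4-fold. The simulated noise was drawn independently for each gene, so these shares leave out the correlation between genes. For aged against 5 weeks these shares were 7%, 64% and 95%, and for 8 weeks against 5 weeks 9%, 59.5% and 97%. For the interaction, 59.5% of 4-fold and 86% of 8-fold changes were recovered. The labels describe separate samples, and nothing says that each came from its own animal, so p-values measure only the spread between these samples.

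A total of 42 gene lists, covering pathways, cell type markers and signs of RNA quality, was fixed before the data were examined, and 35 had at least 5 tested members. They were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists within each contrast. Camera with an estimated correlation and fry, which asks if the genes of a list move one way without comparing them with other genes, were alternatives. All list calls ended with the estimated correlation, and the p-value of each list described is given beside it. A list's count of called genes is over all genes tested, and the count adjusted over the list alone follows it.

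Genes are named by a rule fixed before the data were examined. In each contrast these are the 8 genes with the largest rise and the 8 with the largest fall that passed the threshold, had a mean CPM of at least 5 in the higher group and moved the same way in both sets, leaving out unnamed gene models, pseudogenes and immunoglobulin or T cell receptor segments. Up to 4 called members of each list with the smallest p-values may be named too, and for a list with none its most abundant member. Esr1, Pgr, Cdkn2a, Cdkn1a, Mki67, Ltf, C3, C4b, Col1a1 and Col3a1 were fixed by name.

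Overlap of exons with other genes was measured on the annotation, since reads of overlapping genes cannot be told apart without strand. Sprr2, immunoglobulin, complement C4 and MHC genes belong to families with near-identical copies, and how the authors' counting split reads between copies is not given in the sources used here, so their levels are uncertain. The gene tests were repeated with other pseudocounts, filters, scalings, weights and designs, within each set, with the mean of the estrogen-responsive list as a covariate, with the replicate number as a block, and with each library left out in turn. Each gene test and list test was also repeated on 100 splits of the compared libraries into groups of the same sizes, drawn with a fixed seed. Columns attached by file, weights from limma's voom on recomputed reads, and a fit without 5w replicate 5 and aged replicate 7, which lay nearest the other set on the leading component, were alternatives chosen after the data were seen.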

Results

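The question was which genes of the mouse uterus differ between old animals and animals of 5 or 8 weeks. RNA levels of 12791 genes were compared between 7 uteri of 5-week-old, 7 of 8-week-old and 6 of aged mice, in CPM, given as mean ± SD. The 2 sets of libraries differed more than the age groups did. Principal component 1 held 48.2% of the variance and parted the sets, with scores of 51.4 to 91.9 in the 6 libraries of the earlier set and of -63.9 to 15.6 in the 14 of the later set, and component 2 held 20.5%. The set term was called for 7512 genes, of which 2619 were higher and 4893 lower in the later set. Libraries of the same group and set correlated with a median r of 0.926 (0.849 to 0.980) across genes, and libraries of different sets with a median of 0.782.

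**Figure D1:**
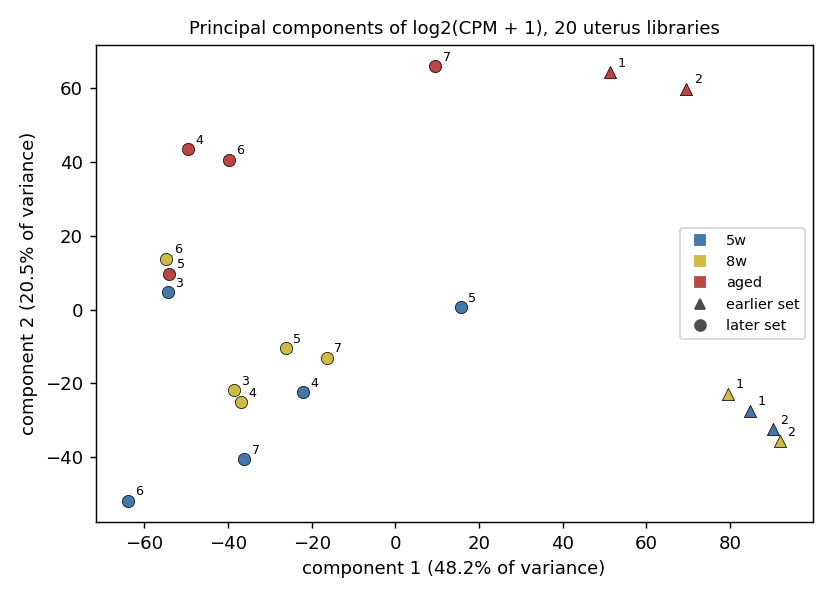
Scores of the 20 libraries on principal components 1 (48.2% of variance) and 2 (20.5%) of log2(CPM + 1), coloured by age, with triangles for the earlier and circles for the later set. The sets part along component 1.

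Compared with uteri of 8-week-old mice, aged uteri had more RNA of antibody genes and of the complement gene C4b and less RNA of cell cycle genes. Igkc, the constant region of the kappa antibody chain (GRCm38 chromosome 6, 70726435 to 70726966, plus strand), averaged 58.0 ± 97.9 CPM (n = 7) at 8 weeks and 1011 ± 1068 CPM (n = 6) in aged uteri, a log2 fold change of 4.67 ± 0.58 (SE). Jchain, which joins antibody units into polymers, rose from 14.7 ± 15.5 to 221 ± 228 CPM, by 3.81 ± 0.53 on the log2 scale. Sprr2b, a cornified envelope protein of epithelium that estrogen induces in the uterus (chromosome 3, 92316620 to 92318085, plus strand), averaged 62.2 ± 57.6 CPM at 8 weeks and 1.27 ± 0.489 CPM in aged uteri, a log2 fold change of -4.21 ± 0.69. C4b, a component of the classical complement pathway (chromosome 17, 34728380 to 34743882, minus strand), rose from 56.8 ± 31.4 to 334 ± 200.2 CPM, by 2.56 ± 0.40. In all, 2179 genes differed, 1099 higher and 1080 lower in aged uteri, of which 448 and 372 changed at least 2-fold. Quantile normalization gave 1167 higher and 1322 lower genes and median centring 1193 and 1347. With the estrogen-responsive list as covariate they were 682 and 1163 and in the later set alone 50 and 130, so which direction held more genes depended on the setting. The count was 540 with columns attached by file and 950 with no set term. Attaching by file also moves the columns of aged replicates 2 and 5 to the other set and that of 5w replicate 3 into the aged group. The count moved by over 1.5 times when aged replicate 1 (1285), 8w replicate 1 (1432) or 8w replicate 2 (1348) was left out, and within the later set alone (4 aged and 5 8-week libraries) 180 genes were called, against 3588 within the earlier set alone (2 and 2).

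Among the genes eligible to be named, the largest rises after Igkc and Jchain were those of Igha (log2 fold change 3.47 ± 0.70, adjusted p = 0.00245) and Ighm (3.08 ± 0.48, adjusted p = 0.000407), the heavy chains of antibodies A and M. Igkc passed with an adjusted p of 0.000141 and changed by 4.55 within the earlier set and 4.70 within the later set, and 4 of 6 aged libraries lay above every younger one. Pigr, the epithelial receptor that carries polymeric antibody into the lumen, rose by 1.82 ± 0.45 (adjusted p = 0.00992). Slc27a2, a fatty acid transporter and acyl-CoA synthetase (chromosome 2, 126552407 to 126588243, plus strand), rose from 10.1 ± 11.2 to 72.0 ± 53.6 CPM (2.88 ± 0.53, adjusted p = 0.00141) and shares 11.2% of its exon length with a gene on the other strand. Fmo2, a flavin monooxygenase, and Pamr1, a secreted peptidase-like protein, rose 6.74-fold each, with log2 changes of 5.04 and 4.87 within the earlier set and 1.68 and 1.77 within the later set. Serpina9, a protease inhibitor of B cells, rose 6.51-fold (adjusted p = 0.00299). In the list of plasma cell and immunoglobulin genes, 4 of 9 members tested rose and 0 fell, 7 rose when adjusted over the list alone, and the median was 0.70 (adjusted p = 0.539 with an estimated correlation). Beside these, all 4 red blood cell genes tested rose, 4 of them when adjusted over the list alone, with a median of 1.64, while 0 of 13 T and NK cell markers passed and 0 of 4 B cell markers did, also when adjusted over the list alone. The full lists held 28 T and NK cell, 16 B cell and 22 plasma cell and immunoglobulin genes. The rest were not among the genes deposited, so a marker silent in any library could not be seen to rise. Reads of the near-identical immunoglobulin genes cannot be assigned with certainty.

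Genes of cell division fell as a group. Of 36 cell cycle genes tested, 34 fell and 0 rose, 35 fell when adjusted over the list alone, and the median log2 fold change was -2.55 (adjusted p = 0.301 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, dropped from 99.2 ± 75.0 to 10.2 ± 10.9 CPM (-3.48 ± 0.36, adjusted p = 7.41e-05), and all 6 aged libraries lay below every younger library. Ube2c shares 22.8% of its exon length with Tnnc2 on the other strand. Mki67, the Ki-67 antigen of cycling cells (chromosome 7, 135689784 to 135716361, minus strand), dropped from 155 ± 96.6 to 26.7 ± 28.9 CPM (-3.00 ± 0.45), with -2.71 within the earlier and -3.13 within the later set, and 5 of 6 aged libraries lay below every younger one. Falls of about the same size were measured for the mitotic kinase Cdk1 (-3.31 ± 0.42), its partner cyclin Ccnb1 (-3.35 ± 0.46), the mitotic kinase Pbk (-3.37 ± 0.46), the replication factor Pclaf (-3.31 ± 0.45) and the nucleotide reductase Rrm2 (-3.17 ± 0.49). Lmnb1, a lamin of the nuclear envelope that senescent cells lose, fell by 1.49 on the log2 scale (adjusted p = 0.00262), and Cdkn1a, an inhibitor of the cell cycle, did not pass (0.19 ± 0.19, adjusted p = 0.518). In the list of senescence and secretory genes, 4 of 15 rose and 2 fell, the same numbers as when adjusted over the list alone, and the list was not called (camera adjusted p = 0.725).

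Genes of hormone response went both ways. Sprr2b passed with an adjusted p of 0.000618, with -4.58 within the earlier and -4.01 within the later set, and all 6 aged libraries lay below every younger one. Sprr2a3, of the same near-identical family, changed by -3.37 ± 0.86 (adjusted p = 0.0119). Ltf, lactoferrin, which estrogen also induces (chromosome 9, 111019271 to 111042767, plus strand), went the other way, from 2212 ± 1041 to 6147 ± 2924 CPM (1.43 ± 0.41, adjusted p = 0.0228). The call of Ltf ended without 8w replicate 1 (adjusted p = 0.0634), aged replicate 1 (0.0536) or aged replicate 6 (0.0572). Of 18 estrogen-responsive genes tested, 1 rose and 5 fell, 1 and 5 when adjusted over the list alone, and the list was not called (median -0.36, camera adjusted p = 0.0662). The estrogen receptor Esr1 (0.27 ± 0.21, adjusted p = 0.381) and the progesterone receptor Pgr (-0.03 ± 0.44, adjusted p = 0.973) did not pass, and 0 of 10 progesterone-responsive genes did, also when adjusted over the list alone. Among 9 steroid hormone receptors 1 rose, also when adjusted over the list alone, the mineralocorticoid receptor Nr3c2 (1.54 ± 0.30, adjusted p = 0.00194).

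**Figure D2:**
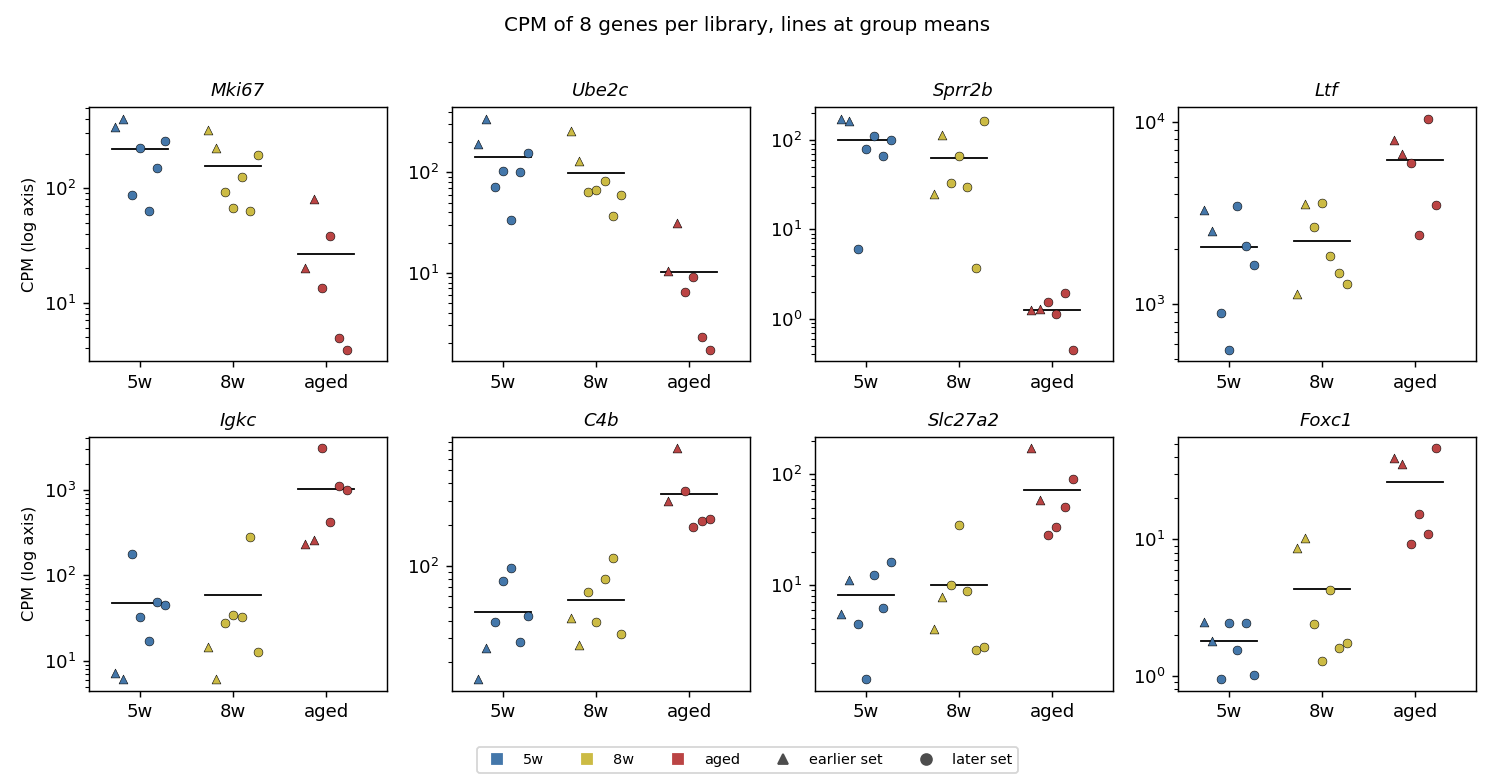
CPM of Mki67, Ube2c, Sprr2b, Ltf, Igkc, C4b, Slc27a2 and Foxc1 in each library on a log axis, by age group, with lines at the group means. Aged libraries lie below all younger ones for Ube2c and Sprr2b and above all for C4b.

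Lists of biosynthetic and energy metabolism were called lower. Of 21 genes of endoplasmic reticulum stress and chaperones, 14 fell, 15 when adjusted over the list alone, and the median was -0.62 (adjusted p = 0.307 with an estimated correlation). Hspa5, the main chaperone of that compartment, dropped from 1521 ± 389 to 729 ± 194 CPM (-1.04 ± 0.18, adjusted p = 0.000784), and Manf, a secreted stress factor, changed by -1.33 ± 0.23. Of 20 genes of cholesterol biosynthesis, 7 fell, 12 when adjusted over the list alone, with a median of -0.89 (adjusted p = 0.539 with an estimated correlation). They included the sterol oxidase Msmo1 (-1.73 ± 0.39, adjusted p = 0.00563). Of 48 genes of oxidative phosphorylation, 9 fell, 14 when adjusted over the list alone, with a median of -0.30 (adjusted p = 0.539 with an estimated correlation). Cox5a, a subunit of cytochrome c oxidase, changed by -1.0 ± 0.17 (adjusted p = 0.000657), all 6 aged libraries lay below every younger one, and 12.8% of its exon length is shared with a gene on the other strand. The list of genes that mitochondria encode was called higher, with 2 of 7 members higher, also when adjusted over the list alone, and a median of 0.42 (adjusted p = 0.706 with an estimated correlation), led by mt-Nd6, a subunit of complex I (0.83 ± 0.19, adjusted p = 0.00626). Nuclear copies of mitochondrial genes, and the overlap of opposite strands in that genome, leave their levels uncertain.

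The collagen list was called lower. Of 18 collagen genes, 6 fell and 0 rose, 11 fell when adjusted over the list alone, and the median was -0.81 (adjusted p = 0.539 with an estimated correlation). Col3a1, the fibrillar collagen of distensible tissues (chromosome 1, 45311538 to 45349706, plus strand), dropped from 2764 ± 626 to 1371 ± 694 CPM (-1.15 ± 0.30, adjusted p = 0.0127), and Col6a6, a chain of beaded-filament collagen, changed by -1.50 ± 0.33. Col1a1, the main fibrillar collagen, did not pass (-0.95 ± 0.35, adjusted p = 0.0656) but did without 5w replicate 5 (adjusted p = 0.0223) or 8w replicate 4 (0.0442). Loxl2, a collagen crosslinking enzyme, changed by -1.53 ± 0.29 (adjusted p = 0.00168), and of 23 matrix crosslinking, matricellular and elastic fibre genes 5 fell and 1 rose, 6 and 1 when adjusted over the list alone. That list was not called, and its median was positive (0.11) while its mean was negative (-0.23), as was the direction of its test. Timp1, an inhibitor of matrix metalloproteinases, changed by -1.51 ± 0.32 (adjusted p = 0.00384), and of 15 metalloproteinase and inhibitor genes 2 rose and 1 fell, 4 and 3 when adjusted over the list alone. Tgfbi, a matrix protein that TGF-beta induces, rose by 2.32 ± 0.48 (adjusted p = 0.00314), and of 22 TGF-beta and BMP genes 4 rose and 0 fell, the same when adjusted over the list alone, with a median of 0.31 (adjusted p = 0.706 with an estimated correlation).

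The lists of antigen presentation, complement and lymphatic vessel genes were called higher. Of 21 MHC antigen presentation genes, 10 rose and 0 fell, 11 rose when adjusted over the list alone, and the median was 0.58 (adjusted p = 0.539 with an estimated correlation). Cd74, the invariant chain of class II molecules, rose by 1.66 ± 0.38 (adjusted p = 0.00556) and H2-Ab1, a class II beta chain, by 1.41 ± 0.36. Of 16 complement genes 5 rose, also when adjusted over the list alone, with a median of 0.68 (adjusted p = 0.539 with an estimated correlation). C4b rose 5.90-fold (adjusted p = 0.000448), with 3.77 within the earlier and 1.98 within the later set and all 6 aged libraries above every younger one, though its near-identical copy C4a leaves its level uncertain. C3, the central complement component, did not pass (0.84 ± 0.53, adjusted p = 0.283), with 2.59 within the earlier and 0.06 within the later set. Of 9 lymphatic endothelial markers 6 rose, 8 when adjusted over the list alone, with a median of 1.19 (adjusted p = 0.539 with an estimated correlation), among them the guidance protein Reln (1.91 ± 0.38, adjusted p = 0.00222) and the matrix glycoprotein Mmrn1 (1.49 ± 0.35). Among markers of other cell types, 1 of 18 vascular endothelial genes rose and 1 fell, also when adjusted over the list alone, 2 of 20 macrophage and dendritic cell genes rose, and none of these 20 passed when adjusted over the list alone. Of 27 interferon response genes 1 fell, 0 when adjusted over the list alone, and of 16 chemokines 4 rose and 1 fell, 4 and 2 when adjusted over the list alone. The vascular, macrophage, interferon and chemokine lists were not called.

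Lists of Wnt signalling, adipocyte and circadian clock genes were called higher. Of 22 Wnt signalling genes, 4 rose and 2 fell, 5 and 2 when adjusted over the list alone, with a median of 0.76 (adjusted p = 0.706 with an estimated correlation). Dkk3, a secreted Dickkopf family protein, rose by 1.63 ± 0.34 (adjusted p = 0.00341) and Wnt16, a Wnt ligand, changed by -1.61 ± 0.34 (adjusted p = 0.00394). Of 6 adipocyte markers 3 rose, 5 when adjusted over the list alone, with a median of 1.12 (adjusted p = 0.539 with an estimated correlation). They were led by the hormone-sensitive lipase Lipe (1.18 ± 0.30, adjusted p = 0.0120), which shares 15.6% of its exon length with another gene. Plin4, a lipid droplet protein, passed (1.70 ± 0.54, adjusted p = 0.0351), but not without 8w replicate 1 (adjusted p = 0.0731), 8w replicate 2 (0.0889), 8w replicate 4 (0.0573), aged replicate 1 (0.104), aged replicate 2 (0.050) or aged replicate 4 (0.0702). Of 17 circadian clock genes 9 rose and 0 fell, the same when adjusted over the list alone, with a median of 0.96 (adjusted p = 0.539 with an estimated correlation). Their changes ran from -0.88 to 2.29. Arntl, which peaks opposite to Nr1d1, changed by -0.46 and did not pass (adjusted p = 0.245). A difference in the time of day at dissection is therefore not told apart from a higher level of clock genes. The clock repressor Nr1d1 rose by 2.29 ± 0.45, the repressor Bhlhe41 by 1.69 ± 0.29 and the output factor Hlf by 1.95 ± 0.48. Hlf changed by 4.24 within the earlier and 0.90 within the later set, and 19.1% of the exon length of Bhlhe41 is shared with a gene on the other strand.

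No list of markers of the uterine tissue layers was called. Median log2 changes were 0.73 for mesothelial, 0.41 for smooth muscle, 0.29 for ciliated cell and oviduct, 0.16 for glandular and 0.13 for endometrial stromal markers. Of 20 luminal and general epithelial markers 1 rose and 0 fell, with a median of -0.23. Of 7 glandular markers 2 rose, Pigr among them, and 1 fell. Of 17 endometrial stromal markers 2 rose, of 19 smooth muscle markers 1, of 9 mesothelial markers 1 and of 6 ciliated cell and oviduct markers 0, and none in these 4 lists fell. Of 6 skeletal muscle markers 1 rose and 1 fell, of 9 Hedgehog genes 1 rose, of 20 immediate early genes 2 rose, and 0 of 57 cytosolic ribosomal protein genes passed. Adjusted over the list alone, 0 luminal, 2 glandular, 1 stromal, 1 smooth muscle, 1 mesothelial, 1 skeletal muscle, 0 ciliated, 0 ribosomal, 0 Hedgehog and 2 immediate early members rose, and 1 glandular and 1 skeletal muscle members fell. None of these lists was called by camera. Camera called 14 of 35 lists, those given above with a second p-value, 9 higher and 5 lower in aged uteri, 0 with an estimated correlation, and fry called 10 of the 14.

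**Figure D3:**
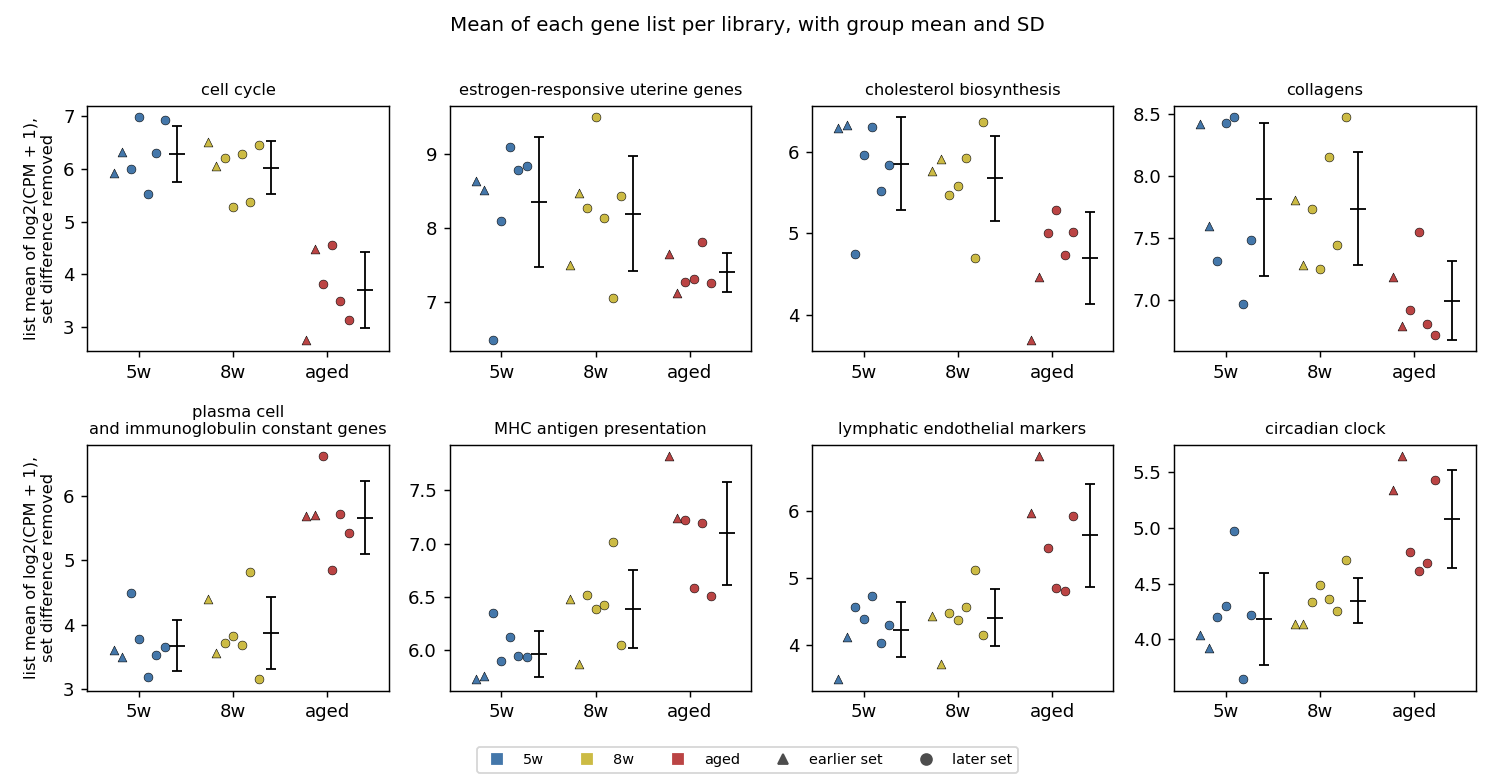
Mean log2(CPM + 1) of 8 gene lists in each library after removal of the set difference, by age group, with group mean and SD. The cell cycle list is lowest in aged uteri and the plasma cell and MHC lists are highest there.

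Compared with uteri of 5-week-old mice, aged uteri again had more RNA of antibody genes and of C4b and less RNA of cell cycle genes. Igkc rose from 47.9 ± 60.2 CPM (n = 7) to 1011 ± 1068 CPM (n = 6), by 4.66 ± 0.58 (SE) on the log2 scale. Sprr2b averaged 99.8 ± 57.9 CPM at 5 weeks and 1.27 ± 0.489 CPM in aged uteri (-5.10 ± 0.69). Foxc1, a forkhead transcription factor (chromosome 13, 31806633 to 31812476, plus strand), rose from 1.81 ± 0.671 to 26.3 ± 16.4 CPM (3.01 ± 0.33, adjusted p = 1.27e-05), with 3.64 within the earlier and 2.76 within the later set and 5 of 6 aged libraries above every younger one. In all, 2799 genes differed, 1610 higher and 1189 lower in aged uteri, 623 and 418 of them at least 2-fold, with counts of 1965 to 3284 when each library was left out in turn. The excess of higher genes was lost with quantile normalization (1462 higher and 1492 lower), median centring (1521 and 1634) and the estrogen covariate (707 and 1014). It was also lost in the later set alone (232 and 281). The count was 1366 with no set term. Within the later set alone (4 aged and 5 5-week libraries) 513 genes were called, and within the earlier set alone (2 and 2) 2584.

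The rises of Jchain (3.82 ± 0.53), Ighm (3.55 ± 0.48) and Igha (3.20 ± 0.70) were among the largest, and Igkc had an adjusted p of 2.79e-05. Of 9 plasma cell and immunoglobulin genes 7 rose, also when adjusted over the list alone, with a median of 1.42 (adjusted p = 0.446 with an estimated correlation). Pigr rose by 2.57 ± 0.45 (adjusted p = 0.000626). Of 4 B cell markers 2 rose, 3 when adjusted over the list alone, of 13 T and NK cell markers 2 rose, 1 when adjusted over the list alone, and of 4 red blood cell genes 0 passed, 3 when adjusted over the list alone. Ovgp1, the oviduct glycoprotein, passed (3.40 ± 1.11, adjusted p = 0.0340), with 5.33 within the earlier and 2.53 within the later set. It ceased to pass without 5w replicates 1 (adjusted p = 0.065), 2 (0.0756), 6 (0.0579) or 7 (0.0657), or aged replicates 1 (0.0979), 4 (0.0777) or 7 (0.0589), and it shares 28.7% of its exon length with another gene. Gstm7, a glutathione transferase, passed (2.97 ± 0.94, adjusted p = 0.0285) but not without 5w replicates 1 (0.054), 2 (0.0506), 6 (0.0539) or 7 (0.0577), or aged replicates 2 (0.0797), 4 (0.0644) or 6 (0.063). Slc27a2 rose 7.69-fold (adjusted p = 0.000837).

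Cell division genes fell again. Of 36 cell cycle genes 34 fell, also when adjusted over the list alone, with a median of -2.95 (adjusted p = 0.289 with an estimated correlation). Mki67 dropped from 218 ± 127 CPM to 26.7 ± 28.9 CPM (-3.46 ± 0.45, adjusted p = 3.65e-05), with -3.17 within the earlier and -3.60 within the later set. Ube2c (-3.95 ± 0.36, adjusted p = 7.97e-06), Ccnb1 (-4.13 ± 0.46) and Cdk1 (-3.76 ± 0.42) fell together with the S-phase cyclin Ccna2 (-3.78 ± 0.44), the mitotic cyclin Ccnb2 (-3.68 ± 0.42) and the spindle-associated hyaluronan receptor Hmmr (-3.72 ± 0.48). Ccna2 shares 12.5% of its exon length with Exosc9 on the other strand. Lmnb1 fell by 1.77 on the log2 scale, Cdkn1a did not pass (0.40 ± 0.19, adjusted p = 0.140), and in the senescence list 4 of 15 rose and 3 fell, the same when adjusted over the list alone, with no call of the list.

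Sprr2b passed with an adjusted p of 5.13e-05 and -6.23 within the earlier and -4.60 within the later set, and its relative Sprr2g changed by -4.09 ± 0.56, with all 6 aged libraries below every younger one. Ltf rose from 2061 ± 1110.0 to 6147 ± 2924 CPM (1.63 ± 0.41, adjusted p = 0.00871). Of 18 estrogen-responsive genes 1 rose and 5 fell, the same when adjusted over the list alone, with a median of -0.45. This list was called lower (adjusted p = 0.677 with an estimated correlation). Esr1 (0.36 ± 0.21, adjusted p = 0.212) and Pgr (-0.06 ± 0.44, adjusted p = 0.943) did not pass. Star, the cholesterol carrier of steroid-making cells, rose by 1.92 ± 0.36 (adjusted p = 0.00122) as 1 of 3 ovarian markers tested, and Kit, the stem cell factor receptor, rose by 2.10 ± 0.36 as the sole mast cell and eosinophil marker tested, both also when adjusted over the list alone.

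Of 21 MHC genes 15 rose, also when adjusted over the list alone, with a median of 1.07 (adjusted p = 0.446 with an estimated correlation), led by Cd74 (2.41 ± 0.38, adjusted p = 0.000211) and H2-Ab1 (2.21 ± 0.36). Of 16 complement genes 6 rose, also when adjusted over the list alone, with a median of 0.78 (adjusted p = 0.646 with an estimated correlation). C4b rose from 46.5 ± 30.0 to 334 ± 200.2 CPM (2.92 ± 0.40, adjusted p = 6.50e-05), and C3 did not pass (0.87 ± 0.53, adjusted p = 0.243) but did without 5w replicate 5 (adjusted p = 0.0407). Of 9 lymphatic markers 6 rose, also when adjusted over the list alone, with a median of 1.21 (adjusted p = 0.446 with an estimated correlation), among them the chemokine Ccl21a (2.86 ± 0.57) and Reln (2.34 ± 0.38). The list of macrophage and dendritic cell markers was called higher, with 3 of 20 members higher and 1 lower, 8 and 1 when adjusted over the list alone, and a median of 0.73 (adjusted p = 0.684 with an estimated correlation). Csf1r, the receptor for macrophage growth factor, rose by 1.15 ± 0.32 (adjusted p = 0.0149) and shares 15.1% of its exon length with Hmgxb3. Msr1, a scavenger receptor, changed by -0.88 ± 0.28 (adjusted p = 0.0316). It ceased to pass without 5w replicate 1 (0.0663), 5w replicate 2 (0.0694), 5w replicate 4 (0.0519), 5w replicate 6 (0.0514), 5w replicate 7 (0.0679), aged replicate 1 (0.0587), aged replicate 2 (0.0585), aged replicate 6 (0.0760) or aged replicate 7 (0.0769). The interferon response list was called lower, with 3 of 27 members lower, 2 when adjusted over the list alone, and a median of -0.70 (adjusted p = 0.677 with an estimated correlation), among them the ubiquitin-like modifier Isg15 (-1.64 ± 0.47) and the antiviral GTPase Mx1 (-1.49 ± 0.42). Of 16 chemokines 7 rose and 2 fell, 8 and 4 when adjusted over the list alone, with no call of the list.

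Of 18 collagen genes 8 fell, 11 when adjusted over the list alone, with a median of -0.91 (adjusted p = 0.566 with an estimated correlation). Col3a1 dropped from 3209.5 ± 1089 to 1371 ± 694 CPM (-1.33 ± 0.30, adjusted p = 0.00382). Col1a1 passed (-1.15 ± 0.35, adjusted p = 0.0239) but not without 5w replicate 1 (adjusted p = 0.0621) or aged replicate 2 (0.0674). Eln, elastin, changed by -1.72 ± 0.43 (adjusted p = 0.00772). Of 20 cholesterol biosynthesis genes 12 fell, 16 when adjusted over the list alone, with a median of -1.03 (adjusted p = 0.446 with an estimated correlation). Of 48 oxidative phosphorylation genes 17 fell, 19 when adjusted over the list alone, with a median of -0.38 (adjusted p = 0.446 with an estimated correlation), and Cox5a changed by -1.04 ± 0.17. Of 7 mitochondrially encoded genes 2 rose, 4 when adjusted over the list alone, with a median of 0.50 (adjusted p = 0.677 with an estimated correlation). Of 21 endoplasmic reticulum genes 9 fell and 1 rose, 13 and 1 when adjusted over the list alone, with a median of -0.47 (adjusted p = 0.446 with an estimated correlation), and Manf changed by -0.92 ± 0.23.

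Of 22 Wnt genes 6 rose and 2 fell, 12 and 2 when adjusted over the list alone, with a median of 1.01 (adjusted p = 0.677 with an estimated correlation). Dkk3 rose by 1.85 ± 0.34 and Wnt16 changed by -2.0 ± 0.34. Tgfbi rose by 2.58 ± 0.48, and of 22 TGF-beta and BMP genes 4 rose, also when adjusted over the list alone, with a median of 0.41 (adjusted p = 0.684 with an estimated correlation). Of 17 clock genes 9 rose and 0 fell, 9 and 1 when adjusted over the list alone, with a median of 1.11 (adjusted p = 0.566 with an estimated correlation). Their changes ran from -0.98 to 2.71, and Arntl changed by -0.32 and did not pass (adjusted p = 0.404). Nr1d1 rose by 2.71 ± 0.45 (adjusted p = 0.000373). The clock output factor Dbp rose by 2.20 ± 0.49 (adjusted p = 0.00358), with 4.78 within the earlier and 1.02 within the later set, and shares 18.0% of its exon length with Sphk2. Camera called 16 of 35 lists, 9 higher and 7 lower in aged uteri, 0 with an estimated correlation, and fry called 14, of which 13 were among the 16.

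Other lists were not called against 5-week uteri. Of 6 adipocyte markers 2 rose, also when adjusted over the list alone. Of 17 stromal markers 3 rose, of 18 vascular markers 3 rose and 1 fell, and of 6 ciliated cell and oviduct markers 2 rose, the same numbers as when adjusted over the list alone. Of 19 smooth muscle markers 3 rose, 2 when adjusted over the list alone. Of 20 luminal epithelial markers 1 rose and 1 fell, and 0 passed when adjusted over the list alone. Of 7 glandular markers 2 rose and 1 fell, also when adjusted over the list alone, with a negative median (-0.21) and a positive mean (0.24) and test. Of 23 matrix crosslinking, matricellular and elastic fibre genes, Eln among them, 2 rose and 6 fell, 2 and 8 when adjusted over the list alone, with a positive median (0.04) and a negative mean (-0.22) and test.

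Most genes called against 1 younger group were called against the other. Of the 1099 genes higher in aged than in 8-week uteri and the 1610 higher than in 5-week uteri, 996 were shared, and of the 1080 and 1189 lower genes 923 were. Independent lists of these sizes would share 138 and 100.4 genes. Both comparisons use the same 6 aged libraries, which alone raises the overlap. With the aged libraries divided into separate parts of 3, 1 compared with each younger group, a median of 63.5 higher genes (37 to 160 over 12 divisions) and 146 lower genes (90 to 247) was shared, against medians of 5.62 and 6.93 for independent lists of those sizes.

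Uteri of 8-week-old and 5-week-old mice (n = 7 each) were not told apart gene by gene. None of the named genes passed: Mki67 changed by -0.46 ± 0.43 (SE) on the log2 scale, Ltf by 0.20 ± 0.39, C4b by 0.36 ± 0.39, C3 by 0.03 ± 0.51, Col1a1 by -0.20 ± 0.33, Col3a1 by -0.18 ± 0.28, Cdkn1a by 0.20 ± 0.18, Esr1 by 0.09 ± 0.20 and Pgr by -0.03 ± 0.42. By limma 0 of 12791 genes were called, 135 had an unadjusted p under 0.05, and limma's voom on recomputed reads also called 0. Those 135 are fewer than the share of 0.05 expected if no gene changed, and the cause was not tested. The median 95% confidence interval of a gene reached 0.44 on either side on the log2 scale, and 59.5% of 2-fold changes were recovered on simulated data, so smaller changes could go undetected. The simulated noise was independent between genes, so the share recovered in these libraries may differ. Camera called 7 lists, though no member passed over all genes or adjusted over the list alone, and fry called 0. Lower at 8 weeks were the interferon list (median -0.37, adjusted p = 0.352 with an estimated correlation), the cell cycle list (-0.37, adjusted p = 0.990 with an estimated correlation), the adipocyte list (-0.59, adjusted p = 0.352 with an estimated correlation), the cholesterol list (-0.17, adjusted p = 0.990 with an estimated correlation) and the oxidative phosphorylation list (-0.04, adjusted p = 0.990 with an estimated correlation). Higher were the MHC list (0.46, adjusted p = 0.352 with an estimated correlation) and the endoplasmic reticulum list (0.26, adjusted p = 0.352 with an estimated correlation).

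The aged mice of the earlier set were 60 to 75 weeks old and those of the later set 79 weeks, so the difference of aged from younger uteri was compared between sets. Clock genes were among those that differed. The differences of Hlf and Dbp between aged uteri and the mean of both younger groups were larger in the earlier than in the later set, by interactions of -3.08 and -3.26 on the log2 scale (later minus earlier, adjusted p = 0.0304 and 0.0304). In all, 54 genes differed, 7 with a higher and 47 with a lower aged difference in the later set, and 1804 had an unadjusted p under 0.05. With columns attached by file 1571 differed, 1019 higher and 552 lower, with the estrogen covariate 201, and after removal of GC content and length trends 303. Attaching by file puts the columns of aged replicates 2 and 5 in the other set, which mixes the set difference into the 1571. Of 17 clock genes tested 4 were among the 54, where 0.0718 would fall by chance (exact hypergeometric test, p = 6.48e-07, over genes that are not independent). Only the clock list was put to this test, so the p-value does not account for the choice of that list. The earlier set held 2 aged libraries, and the count rested on single libraries: it was 0 without 5w replicate 2, 8w replicate 2, aged replicate 1, aged replicate 2 or aged replicate 6, 1 without 5w replicate 1, and 16 to 31 without 5w replicate 4 (30), 5w replicate 7 (29), 8w replicate 5 (16), 8w replicate 6 (31) or aged replicate 4 (29). Without 5w replicate 5 it was 90, without 8w replicate 1 it was 82, and without aged replicate 5 it was 126. Age and set cannot be told apart here.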

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

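For the circadian pattern, the test that left out a single aged library was chosen only after the result was seen. The tests on GC content and length and on the time of day were fixed before.

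Values far from the others of their group were sought in 297 groups of 6 or 7 libraries, for 64 genes and 35 lists on the log2 scale with the set difference removed. The gap from the outlying library to its nearest neighbour was divided by the range of the group. Such a search picks about 1 in 20 groups by chance, here 14.85, and it picked 24, of which 9 were for 5w replicate 3 and 3 each for 8w replicate 4, 8w replicate 6 and aged replicate 7.

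In 5w replicate 3, Gstm7 was high (gap 0.798 of the range, 335 CPM against 2.84 to 14.3 in the other 6 libraries), as were Igha (0.620, 265 CPM against 11.3 to 65.1), Jchain (0.623, 66.3 CPM against 1.80 to 16.9) and Tgfbi (0.589, 145 CPM against 17.8 to 42.7). Sprr2b was low there (0.812, 6.07 CPM against 65.8 to 174), as were Msmo1 (0.571, 22.7 CPM against 54.1 to 193), Mx1 (0.637, 4.61 CPM against 16.5 to 39.1), the estrogen-responsive list (0.618) and the glandular epithelial list (0.649). Gstm7, Igha, Jchain, Tgfbi, Sprr2b, Msmo1 and Mx1 of this library were displaced toward the aged mean. So were the cholesterol list (mean 4.17, against 4.95 to 5.73 in the other 5-week and 4.16 to 4.71 in the aged libraries of the later set) and the Wnt list (5.27, against 3.54 to 4.44 and 4.04 to 5.36). Its column was taken as a 5-week library by its header but lies in the file attached to aged replicate 7. Other values lay with the younger libraries: the cell cycle list mean was 5.40, against 2.54 to 3.96 in the aged libraries of the later set, and C4b was at 39.1 CPM, against 194 to 724 in the aged libraries. That file shares the shift along the sample names with every other file whose header names another sample. Its attachment is thus no separate sign of an aged library, but the values of 5w replicate 3 alone do not settle its age.

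Among the other 5-week uteri, Fmo2 was low in replicate 1 (0.745, 5.81 CPM against 30.3 to 62.0), Csf1r was low in replicate 6 (0.572, 36.0 CPM against 35.0 to 92.8) and the luminal epithelial list was high in replicate 5 (0.572). At 8 weeks, Pgr was low (0.656, 25.4 CPM against 108 to 169), Wnt16 high (0.579, 32.5 CPM against 6.74 to 21.7) and the interferon list high (0.672) in replicate 4. In 8w replicate 6, Ighm was high (0.587, 258 CPM against 10.9 to 53.0), mt-Nd6 was high (0.638, 1053 CPM against 261 to 705) and Msmo1 was low (0.630, 19.9 CPM against 51.1 to 127), and in 8w replicate 7 Kit was high (0.60, 18.3 CPM against 4.96 to 11.3).

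In aged uteri, Esr1 was high (0.629, 457 CPM against 209 to 567), Hspa5 low (0.626, 513 CPM against 569.8 to 918) and the skeletal muscle list low (0.687) in replicate 7. Bhlhe41 was low in aged replicate 5 (0.642, 2.70 CPM against 9.51 to 56.8) and Col1a1 in aged replicate 2 (0.634, 1031 CPM against 281 to 1742). Esr1, Col1a1 and, in 5w replicate 6, Csf1r were not extreme in CPM and stood out only with the set difference removed.

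The difference of aged from younger uteri differed between the sets for 54 genes by a test of the difference itself. Among the named genes these were Dbp (-3.26 on the log2 scale, later minus earlier set) and Hlf (-3.08). The mean of the 17 clock genes differed by -0.90 (95% interval -1.63 to -0.16). Removal of GC content and length trends from each library left -0.87 (-1.28 to -0.45), with 50 of the 54 genes among 303 then called, which argues against such a bias as the whole cause. Without the earlier aged library that weakened it more the value was -0.75 (-1.66 to 0.17), so a contribution of that single library stays open. Dissection at another time of day may also contribute: Arntl and Npas2, which peak opposite to Dbp and Nr1d1, changed in the earlier set by -0.92 (-1.86 to 0.01), an interval that reached 0, while the mean of Dbp and Nr1d1 rose by 3.76. Against 8-week and 5-week uteri of that set, Arntl changed by -1.30 and -1.61 and Npas2 by -0.26 and -0.52. Cry1, Nfil3 and Bhlhe40, chosen after their values were seen, also fell there, while most other clock genes rose. The list mean thus averages genes that moved in opposite ways. In the later set the mean of Dbp and Nr1d1 rose by 1.56 (0.71 to 2.40). The mean of Arntl and Npas2 changed there by 0.35 (-0.20 to 0.90). The time of day thus also stays open for the rise of clock genes against younger uteri. Age (60 to 75 against 79 weeks) and batch are confounded with the set and stay open, untested.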

How the results depend on the processing

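Attaching columns by file, voom weights and leaving out both 5w replicate 5 and aged replicate 7 were alternatives chosen only after the data were seen. Attaching by file puts the column of aged replicate 5 in the earlier set and that of aged replicate 2 in the later set. Each correlated more with the set its header names, and the set term was called for 7512 genes. Counts with columns attached by file thus mix the set difference into the aged group.

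With 2179 genes called, aged against 8 weeks gave 950 with no set term, 180 in the later set only, 3588 in the earlier set only, 4384 with array weights and 540 with columns attached by file. Leaving out each library in turn gave 1285 (without aged replicate 1) to 2599 (without aged replicate 5), with 1432 without 8w replicate 1 and 1348 without 8w replicate 2. With 2799 called, aged against 5 weeks gave 1366 with no set term, 513 in the later set only, 5295 with array weights and 1721 with the estrogen-responsive list as covariate. The stricter thresholds keep fewer genes by construction: an adjusted p under 0.01 left 817 and 1200, and a log2 change of at least 1 left 820 and 1041. The earlier set, with 2 libraries per group, called 2584 genes for aged against 5 weeks, and the cause of the shifts other than those of the thresholds was not tested. The other settings stayed within 1.5 times of both counts, with 1651 and 2455 by voom. The comparison of 8 with 5 weeks gave 0 with limma under every setting run, voom included, with 135 genes at an unadjusted p under 0.05.

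The 54 genes that differed between sets became 201 with the estrogen covariate, 303 after removal of GC content and length trends, 1571 with columns attached by file, 106 without 5w replicate 5 and aged replicate 7, and 0 (without 5w replicate 2, 8w replicate 2, aged replicate 1, 2 or 6) to 126 (without aged replicate 5) with 1 library left out. The 1571 mixes the set difference into the interaction, since the columns of aged replicates 2 and 5 change sets there. The cause of the other shifts was not tested.

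The list calls, 14, 16 and 7 for the 3 comparisons, became 0, 0 and 0 with an estimated correlation, which was 0.237 to 0.702 in called lists against the preset 0.01. Fry left 0 for 8 against 5 weeks. The estrogen covariate left 9 of 16 for aged against 5 weeks and reversed the estrogen-responsive list itself (median 0.60), whose members it contains. For 8 against 5 weeks the later set only called 13 and columns attached by file 12. The cause was not tested.

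Replicate numbers did not pair the libraries: over 19 pairs with the same number r ran from -0.505 to 0.279, and 1 of 20 libraries correlated best with its own number. With the replicate block, 1602, 2398 and 0 genes and 19, 16 and 7 lists were called.

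Of the 48 genes named for aged against 8 weeks, 26 lost their call in the later set only, 13 with columns attached by file and 8 with no set term. Of the 45 named for aged against 5 weeks, 15, 4 and 7 did, and 8 did with the estrogen covariate. No called gene among these reversed. Both pseudocounts kept every call of both groups of genes. No filter was a void setting, since the minimum of 1 CPM removed no gene, and the 2 planned count models were not run. Each listed gene had at least 10 reads in every library, and at that floor depth limits the precision of a value.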

Other observations

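The tests of the epithelial list, of the change within each set, of T and NK cell markers and of red blood cell genes were chosen only after the results were seen.

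Other divisions of the compared libraries into groups of the same sizes, 100 per comparison with the real one, were tested. For aged against 8 weeks, 2 of 100 called as many genes as the real 2179, the other being 2275 when 8w replicate 6 changed places with aged replicate 5. For aged against 5 weeks 1 did, the real one, with 2799 against 1499 at most. By these counts chance is unlikely for aged against 5 weeks. It cannot be excluded by count for aged against 8 weeks, where another division called more genes than the real one. That division kept 5 of the 6 aged libraries together, so it is close to the real one, and the remaining divisions called at most 960. In the libraries it exchanged, 47.5% (8w replicate 6) and 47.6% (aged replicate 5) of genes lay nearer the aged mean, as given above. Among the divisions that kept the real number of earlier libraries in each group, 2 of 41 called as many for aged against 8 weeks. That share of 0.0488 comes from a random draw and lies too near 0.05 to decide. For aged against 5 weeks 1 of 43 did, the real one (at most 392 in the others). For 8 against 5 weeks all 100 called at least the real 0 by construction, with 1 at most, so the divisions say nothing about it. For the number of lists called chance cannot be excluded: 57 of 100 divisions called at least 14 lists for aged against 8 weeks (at most 23), 31 called at least 16 for aged against 5 weeks (at most 21) and 88 called at least 7 for 8 against 5 weeks (at most 20). The mean of the cell cycle list changed as much in 1 of 100 divisions, the real one, against both younger groups, with at most 2.19 and 2.12 in the others. The same held for the endoplasmic reticulum, clock and plasma cell lists. Other called lists were matched more often: Wnt in 7 and 6 of 100, mitochondrially encoded in 5 and 7, TGF-beta in 4 and 7. Against 5 weeks the estrogen-responsive and interferon lists were matched in 6 each. For 8 against 5 weeks the cell cycle list was matched in 35 and oxidative phosphorylation in 69.

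The cell cycle list fell by 2.32 on the log2 scale in aged against 8-week uteri (95% interval -3.03 to -1.60). The luminal and general epithelial list changed by -0.046 (-0.60 to 0.50), with members from -0.92 to 1.13. Its lowest member fell less than the mean of the cell cycle list, which argues against a general loss of epithelial cells as the whole cause. Which cells divide cannot be read from such a list. With the estrogen-responsive list mean as covariate the cell cycle list changed by -2.41 (-3.22 to -1.59), so that mean did not account for the fall. It averages members that rose and fell and itself changed by -0.79 (-1.65 to 0.07), so a weaker estrogen response stays open. Within the sets the cell cycle list changed by -2.17 (-3.04 to -1.29) in the later and -2.67 (-5.05 to -0.29) in the earlier. These values argue against a difference between sets. A lower rate of division with age is a candidate explanation that stays open, as does a dose or cycle difference not captured by the estrogen-responsive list, and neither was tested.

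Igkc rose by 4.67 (95% interval 3.30 to 6.04) in aged against 8-week uteri. The T and NK cell list changed by -0.52 (-1.42 to 0.38), but its members ran from -1.85 to 0.82. The 4 B cell markers tested all changed upward, by 0.47 to 0.75, though 0 passed. The lymphatic endothelial list was called higher, with a median of 1.19. The mean of a mixed list cannot decide here, and lymphoid tissue taken along stays open. Red blood cell genes rose by 1.69 (0.76 to 2.62), less than Igkc, which argues against blood as the whole cause for Igkc and leaves a part open. Igkc rose most in its list, whose mean (1.79) lay near that of the red blood cell genes and whose median (0.70) lay below it. For the list as a whole blood therefore stays open. With the estrogen-responsive list mean as covariate Igkc changed by 3.82 (2.66 to 4.98). More antibody-secreting cells in the aged uterus may account for the rise, and age itself stays open as untested.

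Some genes that differed between sets were chosen after their values were seen. Pik3ip1, an inhibitor of PI3-kinase, was higher in aged than in 8-week uteri by 3.46 on the log2 scale in the earlier set and by 1.26 in the later set (interaction -2.39, adjusted p = 0.0304). Lrp8, a lipoprotein receptor, changed by -3.87 and -1.26 (interaction 2.57), and Mvd, of cholesterol biosynthesis, by -2.33 and -0.36 (interaction 2.34). Fos, an immediate early gene, changed by -1.80 and 0.18 (interaction 2.41).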
